A study of Arabidopsis thaliana with 71 samples.

How the data were processed

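RNA was measured by poly(A) RNA sequencing of whole roots cut from 5-day-old Arabidopsis thaliana seedlings kept in continuous light, per the labels. Seedlings of the wild type Col-0 and of 2 alleles of the ethylene receptor gene ETR1 were moved on their nylon filter to new medium. In 1 series the new medium held 1-aminocyclopropane-1-carboxylic acid (ACC, the precursor of ethylene), and in the other the plates were placed in ethylene gas. etr1-3 is an ethylene-insensitive receptor allele and etr1-7 a loss-of-function allele. Roots were harvested at 0, 1, 4 and 24 h, which gave 24 groups of genotype, series and time, and 71 libraries. The labels call the replicates of a group biological replicates, with 2 plates in each, and every group has 3 except ethylene Col-0 at 4 h, which has 2. No untreated library was harvested after 0 h, so each change from 0 h joins the treatment with the time on new medium. The label fields disagree on the doses: ACC is 0.75 µM in the design text and 1 µM in the sample labels, and ethylene is 0.3 ppm in the design text and protocol and 3 ppm in the sample labels. No result uses a dose.

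The values are the authors' deposited estimated counts per locus, 1 column per library, not scaled between libraries. Per the submitters' processing notes, reads were handled with FastQC 0.11.8, MultiQC 1.7, cutadapt 1.18, Salmon 0.12.0 and R 3.6.0 on the genome build TAIR10. The step from transcripts to loci, the order of these tools and the use of strand are not given in the sources used here. The table holds 26669 loci, of which 1749 have no count in any library, and 32.3% of its values are not whole numbers. All 71 columns were used. Totals per library ran from 12.29 M to 25.3 M in the ACC series and from 12.99 M to 25.29 M in the ethylene series (M, 10 to the power 6). Where reads of near-identical copies, overlapping genes or antisense partners could be shared, the split between them rests on the estimation and is uncertain. Intervals and floors in the text cover counting error only. All 26669 loci matched a reference gene table of assembly TAIR10.1, used for symbols and product names only, and 10369 of them have a symbol there. Genes without one are named by locus.

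Counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr on the groups, estimateDisp, a robust quasi-likelihood fit and quasi-likelihood F-tests with Benjamini-Hochberg adjustment over all loci tested, called below 0.05. Each series was fitted on its own with 12 groups, which left 20460 loci in the ACC series and 20640 in the ethylene series. A time course tested 1, 4 and 24 h against 0 h of the same genotype jointly. A gene was called higher or lower at a time when this joint test and the contrast of that time both passed. The difference between genotypes was tested as the change of the mutant from its 0 h minus that of Col-0. In this test, and in that of ACC against ethylene, higher and lower refer to the change and not to the level. ACC was compared with ethylene in Col-0 in a fit of all 24 groups over 20908 loci, each series against its own 0 h. At 0 h, genotypes were compared with series as a term and series with genotype as a term, over 18 libraries and 20073 loci. A sentence that prints an adjusted p without another tool gives the one of the edgeR test. Unless noted, errors of log2 changes are approximate standard errors from the F-test with 3 libraries per group. Errors of CPM (counts scaled to a common total by TMM) are standard deviations.

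A response score measured how far each treated library moved along the Col-0 response of the other series. It is the mean over genes called in Col-0 at that time in the other series of log2 CPM minus the mean of the same genotype at 0 h, with the sign of the Col-0 change and a prior count of 2. Mutant and Col-0 libraries were compared by a two-sided exact permutation test, whose smallest possible p is 0.1. Shared calls were counted per time and direction beside the number that independent lists would share (Fisher's exact test). 16 gene lists with 243 members were written by hand, and a list member is its symbol at the written locus. As a departure from the written rule, by which the reference table decides the locus of a symbol, AT1G12010 (ACO3) and AT4G10270 (WIP4) were kept, because the table gives these symbols to an aconitase gene and to a zinc finger gene. The lists cover ethylene signalling, ethylene response factors, ethylene and ACC synthesis, auxin synthesis and transport, auxin response, root hairs, cell wall and elongation, flavonoids, jasmonate and ethylene defence, low oxygen, touch and handling, the circadian clock, nitrate, type-A response regulators, the mitotic cycle and, as markers of another tissue, shoot photosynthesis. List members called were counted over all loci and adjusted over the list alone, and each list was tested against all other genes with camera of limma 3.58.1 at the preset correlation of 0.01. Camera values were adjusted within 5 families of 288, 192, 48, 32 and 16 tests. Of the calls, 120, 51, 14, 8 and 5 in that order, 12, 0, 4, 0 and 0 held with an estimated correlation.

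The groups, tests, lists and alternatives, and the rule for naming genes, were fixed before the data were examined. The rule names ETR1 first, any member of the ethylene signalling list and up to 4 members of another list with the smallest adjusted p. For Col-0 it names the 4 largest rises and 4 largest falls per time, among called genes with a mean log2 CPM of at least 1 and all treated libraries on the same side of all 0 h libraries. It names 2 of each for the mutants. For differences it names up to 3 per direction and time, and for each mutant at 0 h up to 8 per direction with the same sign in both series. Genes outside this rule are marked where they appear.

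The alternatives were DESeq2 size factors in edgeR, no filter on low counts, the DESeq2 1.42.0 likelihood ratio test, limma voom with sample quality weights, the replicate number as a block, fits over fewer or more groups, each series on its own at 0 h, and leaving out each library in turn. A stricter gene choice of at least 2-fold and a prior count of 0.5 were used for scores and overlaps. After the data were seen, 4 more were added: the mean of the 15 shoot markers as a covariate, leaving out the libraries whose mean marker level lay over the median of all libraries by more than 2 log2 units, the score against the Col-0 0 h libraries, and leaving out single libraries in the scores. Other splits of the same libraries were drawn 100 at a time, and 40 for ACC against ethylene. The tests were checked on counts simulated from 1 real mean per gene over all groups and the real library sizes, with added changes of known size. The changed genes had a mean log2 CPM over 1 and the same change at 1, 4 and 24 h, and the joint test was scored. Of 67 genes changed 2-fold, 91% were recovered in the time course of ACC in Col-0 (20460 loci) and 70.1% in that of ethylene (20640 loci). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No 2 libraries held the same counts, and among 70 pairs of replicates the chi-square per degree of freedom was 4.44 or more.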

Results

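Poly(A) RNA of whole Arabidopsis roots was measured in 71 libraries from 3 genotypes, 2 series and 4 times. Col-0, the ethylene-insensitive receptor allele etr1-3 and the loss-of-function allele etr1-7 were each followed for 24 h on medium with ACC or in ethylene gas. Every group had 3 libraries except Col-0 at 4 h of ethylene with 2, and libraries held 12.29 M to 25.3 M counts in the ACC series and 12.99 M to 25.29 M in the ethylene series (M, 10 to the power 6). ETR1, the receptor gene that carries both mutations, stood at 47.1±2.36 CPM in Col-0, 50.1±2.74 in etr1-3 and 33.0±4.52 in etr1-7 at 0 h of the ACC series. At 0 h of the ethylene series it stood at 47.3±6.17, 47.5±5.03 and 60.9±7.71 CPM in the same order. Both alleles are small changes within ETR1 that need not alter its transcript, so these levels do not check the genotype labels.

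The 15 photosynthesis genes of the shoot list, which mark leaf tissue, varied strongly between root libraries. Their mean level per library ran from 1.64 to 8.82 log2 CPM around a median of 5.03, and the spread within groups (SD) was 0.93 in the ACC series and 1.72 in the ethylene series. 8 libraries lay more than 2 log2 units over the median: ACC Col-0 1 h replicate 2, and in the ethylene series Col-0 0 h replicate 3, Col-0 1 h replicates 2 and 3, Col-0 4 h replicate 3, etr1-3 1 h replicate 3, etr1-3 4 h replicate 3 and etr1-7 4 h replicate 2. These 8 are called shoot-rich in the text, and each main count is also given without them.

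**Figure D1:**
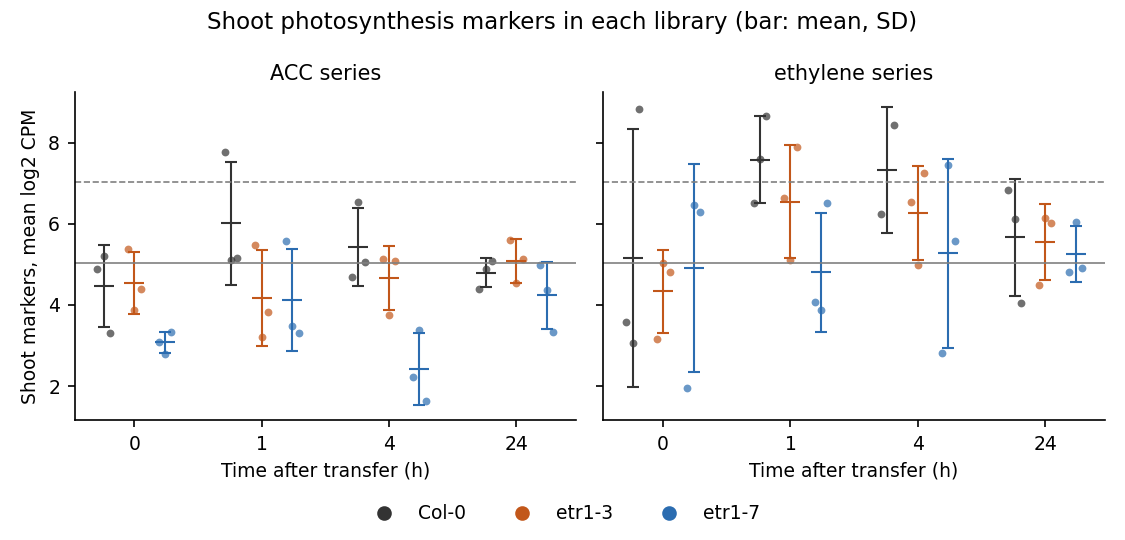
Mean log2 CPM of 15 shoot photosynthesis genes (y axis) in each library by hours after transfer (x axis), with the median of 5.03 as a solid line and 2 log2 units over it as a dashed line. The highest library was ethylene Col-0 0 h replicate 3 at 8.82.

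The first question was which genes changed in Col-0 roots on ACC. ETR1 itself did not pass the test at any time (50.9±4.72 CPM at 1 h, 51.9±8.28 at 4 h, 47.1±2.63 at 24 h). Of the 18 ethylene receptor and signalling genes, 10, 10 and 11 rose at 1, 4 and 24 h and 0 fell. The receptor gene ETR2 rose by 1.89±0.14, 2.1±0.14 and 1.41±0.14 log2 units at these times, and EBF2, whose F-box protein removes the transcription factor EIN3, by 1.71±0.11, 1.39±0.11 and 1.04±0.11. ARGOS and ARL, whose products lower ethylene sensitivity and alter organ size, rose by 3.25±0.26 and 2.66±0.22 at 1 h and remained raised at 24 h (1.76±0.25 and 1.69±0.22). RTE1, which acts on the ETR1 receptor, rose by 1.09±0.16, 1.40±0.16 and 1.3±0.16, the receptor genes ERS2 and ERS1 by 1.17±0.15 and 0.67±0.12 at 1 h, EBF1 by 0.57±0.10, and CTR1 and EIL1 by 0.32±0.09 and 0.28±0.06. RAN1, a copper transporter gene, rose only at 24 h (0.25±0.08). Adjusted over the list alone, 10, 10 and 11 members were higher and 1, 1 and 0 lower. Camera gave an adjusted p of 7.61e-15, 1.18e-10 and 3.14e-09 (adjusted p = 0.0281, 0.0531 and 0.0699 with an estimated correlation).

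Ethylene response factor genes rose with them: 6, 9 and 8 of 13 at 1, 4 and 24 h, and 0 fell (9, 9 and 10 higher and 1, 0 and 0 lower over the list alone). ORA59, an activator of defence genes, rose by 2.1±0.37, 3.27±0.35 and 3.64±0.35, EDF3 by 2.1±0.24 at 1 h, and RAV2 and TEM1 by 0.84±0.08 and 0.92±0.16. For this list the camera adjusted p was 7.53e-09, 1.91e-07 and 4.83e-09 (adjusted p = 0.0345, 0.0531 and 0.0338 with an estimated correlation). When single libraries were left out, the 8 of 24 h ranged from 5 to 8. Of 14 ethylene and ACC synthesis genes, 3, 5 and 4 rose and 2, 2 and 1 fell (0 to 2, 0 to 3 and 1 to 2 fell with single libraries left out). ACO1, which encodes an enzyme that turns ACC into ethylene, rose by 1.72±0.24, 2.31±0.24 and 1.77±0.24, and the ACC synthase gene ACS7 fell by 0.77±0.23 at 4 h and 0.96±0.23 at 24 h. PR4 and the chitinase gene HCHIB, both defence genes, rose at 24 h by 1.83±0.35 and 1.05±0.33, 2 of the 6 genes of that list (1 to 2 with single libraries left out).

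Some genes of the cytokinin, root hair, cell wall and flavonoid lists fell. Of 10 type-A response regulator genes, which respond to cytokinin, 5 fell at 1 h and 0 rose (6 over the list alone, 2 to 5 when single libraries were left out), with ARR3 at −1.56±0.16 and ARR6 at −0.75±0.15, and 0 were called at 4 or 24 h. The camera adjusted p at 1 h was 2.12e-07 (adjusted p = 0.0732 with an estimated correlation). Of 19 root hair genes, 13 fell at 24 h and 0 rose (13 over the list alone, 8 to 13 when single libraries were left out). Among them were the expansin genes EXPA7 (−0.57±0.11) and EXPA18 (−0.71±0.12) and RHD2, the oxidase gene of hair growth (−0.47±0.10), with a camera adjusted p of 6.44e-09 (adjusted p = 0.103 with an estimated correlation). At 1 h 2 of them fell (0 to 3 with single libraries left out), and at 4 h 3 rose (0 to 3) and 1 fell. Cell wall genes fell in 3, 2 and 5 of 16 cases (EXPA14 by 1.03±0.13 and XTH19 by 0.88±0.15 at 1 h; 2 to 3, 1 to 2 and 3 to 7 with single libraries left out), and 1, 0 and 0 rose. Flavonoid genes fell in 1, 1 and 3 of 11 cases (F3H by 0.40±0.11, 0.43±0.11 and 0.76±0.11).

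Auxin, nitrate and low-oxygen genes moved in both directions. Of 17 genes of auxin synthesis and transport, 4 rose at 1 h (2 to 4 with single libraries left out), among them TAA1 (0.68±0.14) and YUC3 (0.61±0.13), and the transporter gene ABCB4 fell at 4 and 24 h (0.80±0.11 and 0.73±0.11). The camera adjusted p of that list at 1 h was 0.000297 (adjusted p = 0.135 with an estimated correlation). IAA2, an auxin-responsive gene, rose at all times (1.09±0.15, 0.95±0.15 and 1.06±0.15), with 2, 1 and 1 of 17 members higher and 3, 2 and 0 lower (the first 2 ranged from 1 to 2, the 3 from 0 to 3 and the last 2 from 0 to 2). The nitrate transporter gene NRT2:1 rose at 4 h alone (4.29±0.69), with LBD39 at 0.77±0.11, and 4 of 20 nitrate genes were higher and 1 lower. ERF71, a transcription factor of low oxygen, fell by 2.62±0.52 at 4 h and 3.75±0.56 at 24 h, and its relative ERF73 rose by 1.29±0.27, 1.99±0.27 and 1.16±0.27. Of 15 low-oxygen genes, 1, 2 and 1 rose and 0, 4 and 3 fell. TCH3, a calmodulin-like touch gene, rose by 1.7±0.39, 2.53±0.40 and 2.05±0.39, with 1, 1 and 3 of 13 touch genes higher (the 3 ranged from 1 to 3) and 0, 1 and 1 lower. Of 13 clock genes 0, 1 and 3 were higher and 0, 1 and 0 lower (ELF3 0.37±0.08 at 24 h, where the 3 ranged from 1 to 3), and of 13 genes of the mitotic cycle only CYCB1;1 was called (0.35±0.10 at 1 h).

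The largest rises outside the lists were those of AT1G22810, an integrase-type DNA-binding gene, by 6.39±1.03 at 1 h, AT5G48430, an aspartyl protease gene, by 5.14±0.47 at 1 h and 5.19±0.47 at 4 h, AT5G40590, a Cys/His-rich C1 domain gene, by 4.87±0.39 at 1 h, and AT2G43890, a pectin lyase-like gene, by 4.41±0.37 at 1 h. The peroxidase gene AT5G19890 rose by 4.87±0.53 and AT1G21320 by 4.60±0.40 at 4 h. At 24 h AT4G33720 went from 3 to 718 counts over the group, 260-fold with a 95% counting interval of 88.5 to 1260, and AT1G26240 from 2 to 406 counts, 220-fold with an interval of 60.6 to 1820, beside AT3G05950 (5.74±1.09) and AT1G26390 (5.60±0.79). The largest falls were AT4G36700 (−2.06±0.56), ABCG16 (−1.89±0.49), the cellulase gene GH9B6 (−1.76±0.30) and the phosphatase gene HAI1 (−1.67±0.36) at 1 h. At 4 h they were the late embryogenesis genes AT4G36600 (−4.74±1.02) and LEA7 (−4.11±0.67) with AT5G01300 (−3.88±0.84) and AT2G18540 (−3.87±0.78), and at 24 h AT2G30766 (−4.26±1.04), the dehydrogenase gene NDB4 (−4.11±0.60), AT5G09570 (−4.03±0.58) and ERF71.

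In all, 5248 of 20460 genes changed in Col-0 on ACC (7892 below 0.05 before adjustment), with 569 higher and 496 lower at 1 h, 991 and 1466 at 4 h, and 1196 and 1263 at 24 h. The count was 4763 without the shoot-rich library of 1 h and lay between 4035 and 4763 when any library was left out, and a fit over both series gave 3414. The counts of 1, 4 and 24 h went down to 362, 705 and 690 higher (without 0 h replicates 2, 4 and 3) and to 265, 1029 and 773 lower (without 1 h replicate 3, 4 h replicate 2 and 24 h replicate 4), and without the shoot-rich library 374 were higher and 286 lower at 1 h. The shoot markers averaged 4.46±1.02 log2 CPM at 0 h, 6.01±1.52 at 1 h, 5.43±0.97 at 4 h and 4.79±0.35 at 24 h, and 0 of the 15 was called. As a list they were higher at 1 h (camera adjusted p = 8.72e-05, adjusted p = 0.531 with an estimated correlation), and without the shoot-rich library the adjusted p was 0.146. No untreated library followed 0 h, so ACC and the time on new medium were not separated here.

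**Figure D2:**
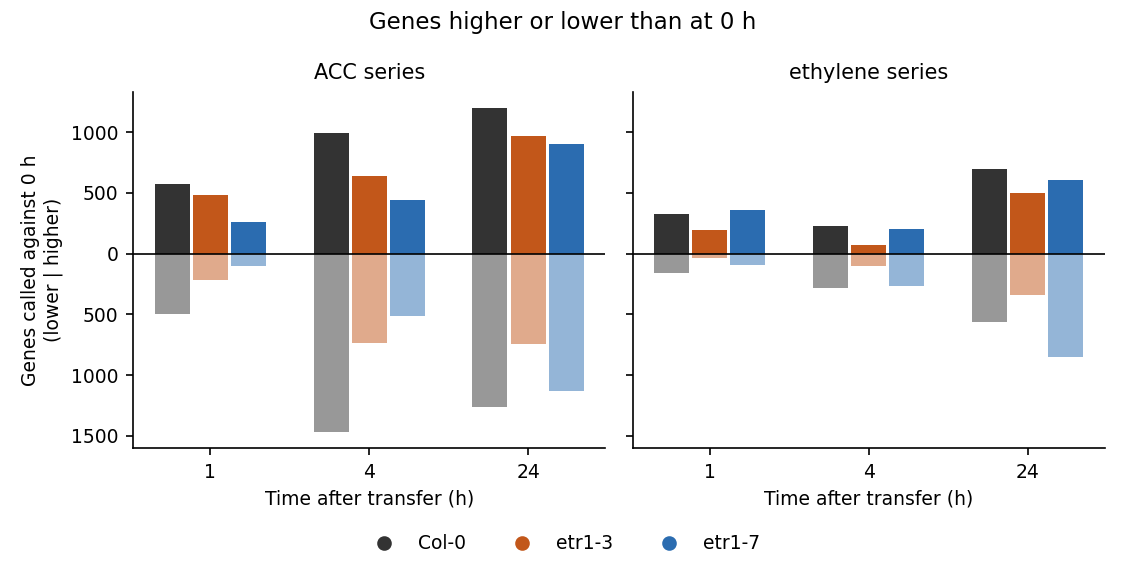
Number of genes called higher (above the line) or lower (below it) than at 0 h (y axis) at 1, 4 and 24 h after transfer (x axis), by genotype and series. Col-0 on ACC had 991 higher and 1466 lower at 4 h, against 229 and 282 in ethylene.

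In etr1-3 on ACC the question was whether the insensitive receptor removed these changes. ETR1 stayed at 49.6±1.59, 47.8±2.34 and 51.4±2.73 CPM at 1, 4 and 24 h and was not called. Of the 18 signalling genes 9, 8 and 7 rose and 0 fell: ETR2 by 1.83±0.15, 1.86±0.15 and 1.57±0.15, EBF2 by 1.39±0.11, 1.02±0.11 and 0.91±0.11, ARL by 1.93±0.24, 1.44±0.24 and 1.26±0.25, and ARGOS by 2.48±0.28 and 1.32±0.29 at 1 and 4 h. ERS1 and ERS2 rose at all times (0.63±0.12 and 0.71±0.16 at 1 h), EIL1 by 0.33±0.06 at 1 h, EBF1 by 0.38±0.10 at 1 h and at 4 h, EIN4 by 0.32±0.08 at 1 h and RAN1 by 0.42±0.08 at 24 h. Over the list alone 11 members were higher at each time and 0 lower, and the camera adjusted p was 1.18e-15, 2.70e-08 and 2.08e-08 (adjusted p = 0.0268, 0.0835 and 0.0835 with an estimated correlation). The response factor genes ORA59 (2.81±0.59 at 4 h, 4.04±0.53 at 24 h), EDF3 (1.82±0.24 at 1 h) and RAV2 (0.58±0.08 at 1 h) rose as well, with 2, 5 and 4 of 13 higher and 0 lower.

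Genes of other lists moved in etr1-3 on ACC as well. ARR3 fell by 1.84±0.17 at 1 h with 4 of 10 type-A genes lower and 0 higher (2 to 6 when single libraries were left out; camera adjusted p = 8.77e-08, adjusted p = 0.0667 with an estimated correlation). NRT2:1 rose by 6.53±0.76 at 4 h with 6 of 20 nitrate genes higher and 0 lower, ERF71 fell by 3.22±0.49 at 4 h, and ACS7 rose at 1 h (0.77±0.22) and fell at 4 h (1.41±0.23). Of 19 root hair genes 1, RHD6, fell at 24 h (−0.50±0.13) and 0 rose, and EXPA7 and RHD2 rose at 1 h (0.44±0.11 and 0.38±0.10; 0 to 2 members with single libraries left out). Outside the lists AT1G22810 went from 1 to 464 counts at 1 h, 409-fold with a 95% counting interval of 73.1 to 16200, and AT1G26240 from 3 to 439 at 24 h, 164-fold with an interval of 55.7 to 798. AT5G40590 (5.25±0.42 at 1 h), AT5G48430 (4.85±0.46 at 4 h) and AT1G26390 (5.99±0.69 at 24 h) rose, and hemb2 (−1.95±0.39) and HAI1 (−1.92±0.37) fell at 1 h, AT5G24640 (−3.87±0.50) and AT3G58150 (−3.85±0.47) at 4 h, and AT5G09570 (−3.86±0.55) and NDB4 (−3.74±0.54) at 24 h. In total 4659 genes changed (7294 before adjustment), with 478 higher and 218 lower at 1 h, 642 and 736 at 4 h, and 964 and 744 at 24 h. The count was 3089 without etr1-3 24 h replicate 3 and otherwise at most 5104, and 4563 in the fit without shoot-rich libraries, where none of its own was left out but the dispersion changed. A fit over the etr1-3 libraries alone gave 2477 and limma voom 7497. Per time the counts went down to 275, 439 and 466 higher (without 0 h replicate 2, the same library and 24 h replicate 3) and 87, 423 and 254 lower (without 0 h replicate 2, 4 h replicate 3 and 24 h replicate 3).

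In etr1-7 on ACC, ETR1 rose by 0.39±0.10 at 4 h and at 24 h. Signalling genes that rose included ETR2, by 0.63±0.13, 0.68±0.13 and 0.48±0.13, EBF2 by 0.66±0.10, 0.37±0.10 and 0.31±0.10, ARGOS by 1.44±0.23 and ARL by 0.92±0.20 at 1 h, RTE1 by 0.71±0.15, 0.61±0.15 and 0.68±0.15 and CTR1 by 0.48±0.09 at 4 h, and RAN1 fell at 1 h (−0.31±0.08). Of 18 members 5, 7 and 5 rose and 1, 0 and 0 fell (8, 8 and 7 higher over the list alone), and with single libraries left out the 3 counts went down to 2. The camera adjusted p was 9.55e-07, 6.97e-05 and 0.00964 (adjusted p = 0.135, 0.253 and 0.489 with an estimated correlation). ERF11 rose by 1.11±0.29, 1.2±0.29 and 2.03±0.29 and ORA59 by 1.09±0.28, 1.2±0.28 and 1.76±0.28, with 4, 2 and 8 of 13 response factor genes higher (1 to 5, 0 to 2 and 2 to 9 with single libraries left out). The auxin synthesis genes YUC9 (1.04±0.13), YUC3 (0.89±0.13) and TAA1 (0.88±0.14) rose at 1 h, and IAA2 at all times (1.05±0.15 at 1 h), as did NRT2:1 at 4 h (3.44±0.81).

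Falls in etr1-7 on ACC included ERF71 (−3.03±0.48 at 4 h, −4.60±0.56 at 24 h), ARR3 (−0.76±0.15 at 1 h), 6 of 11 flavonoid genes at 24 h (F3H −0.92±0.11, TT4 −1.06±0.17), 7 of 16 cell wall genes at 24 h (CESA1 −0.42±0.07) and, at 4 h, 4 of 13 mitotic genes (SYP111 −0.54±0.10, CYC1BAT −0.50±0.10). With single libraries left out the 7 ranged from 4 to 7 and the 4 from 2 to 5. The camera adjusted p of the flavonoid list at 24 h was 0.000241 (adjusted p = 0.244 with an estimated correlation), with a median change of −0.87 and a mean of −0.27. Outside the lists AT1G22810 rose by 6.48±1.02 and AT2G43890 by 4.56±0.41 at 1 h, AT5G48430 by 3.43±0.43 at 4 h and AT4G33720 by 9.48±1.26 at 24 h, where AT1G26240 went from 2 to 318 counts, 169-fold with a 95% counting interval of 46.3 to 1400. GH9B6 (−1.39±0.29) and AT1G53163 (−1.36±0.33) fell at 1 h, AT5G24640 (−3.61±0.50) and AT3G54530 (−3.52±0.53) at 4 h, and AT3G58150 (−5.10±0.56) and AT5G09570 (−4.63±0.58) at 24 h. In total 3479 genes changed (6760 before adjustment), with 260 higher and 105 lower at 1 h, 442 and 515 at 4 h, and 904 and 1129 at 24 h, 3350 without shoot-rich libraries and 2327 to 4319 when single libraries were left out. A fit over the etr1-7 libraries alone gave 1786, a fit over both series 2019 and limma voom 7561. Per time they went down to 129, 181 and 376 higher (each without 0 h replicate 3) and 32, 196 and 608 lower (without 1 h replicate 2, 4 h replicate 2 and 24 h replicate 4), and up to 617 and 749 at 4 h without 0 h replicate 4. Shoot markers averaged 3.07±0.27 log2 CPM at 0 h and 4.12±1.26, 2.42±0.89 and 4.23±0.83 at 1, 4 and 24 h.

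The next question was whether the response on ACC differed between mutant and Col-0. For etr1-3 no gene passed with edgeR: 0 genes differed, with 915 below 0.05 before adjustment, 14 with DESeq2 and 2 with limma voom. ETR2, EBF2 and ARL, called in both genotypes, were not called in this test, where ARL at 4 h rose less in etr1-3 by 1.11±0.33. As a list, however, the signalling genes responded less at 4 h (median −0.19, camera adjusted p = 2.05e-05, adjusted p = 0.377 with an estimated correlation; 1 of 18 lower over the list alone) and so did the response factor genes (median −0.34, camera adjusted p = 2.51e-05, adjusted p = 0.308 with an estimated correlation; 0 over the list alone). The change of root hair genes at 24 h was higher in etr1-3 than in Col-0, where more of them fell (median difference 0.48, camera adjusted p = 2.20e-11, adjusted p = 0.208 with an estimated correlation, 8 of 19 higher over the list alone). That of shoot markers was lower at 1 h (median difference −1.72, camera adjusted p = 6.38e-09, adjusted p = 0.439 with an estimated correlation), the time of the shoot-rich Col-0 library. The count was 1 without Col-0 1 h replicate 2, 24 h replicate 2 or 24 h replicate 4, and 1 without shoot-rich libraries. Of simulated genes with a mean log2 CPM over 1 and a 2-fold difference at all of 1, 4 and 24 h, this test recovered 64.2%, and of 4-fold ones 95.5%. Differences at 1 time only, or in genes of lower counts, were not simulated.

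For etr1-7 on ACC 8 genes differed (1519 before adjustment). At 1 h ETR2 (−1.26±0.19), EBF2 (−1.04±0.15) and ARL (−1.74±0.29) rose less than in Col-0, and at 4 h again (−1.42±0.19, −1.02±0.15 and −1.78±0.29) with RAV2 (−0.64±0.11), AT1G49570 (−3.05±0.61) and AT2G43140 (−2.54±0.43). UGE2, a UDP-glucose epimerase gene, was higher at 1 h (1.13±0.20) and P5CS1, a proline synthesis gene, at 4 h (1.04±0.17). Of 18 signalling genes 3, 3 and 0 were lower at 1, 4 and 24 h (6, 8 and 7 over the list alone), with a camera adjusted p of 1.34e-09, 3.84e-06 and 7.85e-07 (adjusted p = 0.208, 0.377 and 0.377 with an estimated correlation). DESeq2 called 61 genes, limma voom 79, and 3 were left without shoot-rich libraries. The 8 became 18 without etr1-7 1 h replicate 2. They became 5 without etr1-7 0 h replicate 2, 24 h replicate 3 or 4 h replicate 3, and 4 without Col-0 1 h replicate 4, Col-0 4 h replicate 4, Col-0 24 h replicate 3 or etr1-7 1 h replicate 3. They became 3 without Col-0 0 h replicate 2, Col-0 1 h replicate 2 or 3, Col-0 4 h replicate 2 or 3, etr1-7 1 h replicate 4, etr1-7 4 h replicate 2 or 4, or etr1-7 24 h replicate 2, and 2 without Col-0 0 h replicate 3 or 4 or etr1-7 0 h replicate 3.

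In ethylene gas the same question was asked of Col-0. ETR1 stood at 47.2±5.82, 47.2±2.05 and 52.7±7.56 CPM and was not called. ETR2 rose by 1.87±0.10, 1.57±0.11 and 1.69±0.10 at 1, 4 and 24 h, RTE1 by 1.46±0.15, 1.11±0.16 and 1.53±0.15, ARL by 2.43±0.25, 1.61±0.26 and 1.59±0.25, ARGOS by 2.85±0.33, 1.47±0.35 and 1.32±0.32, and EBF2 by 1.61±0.18, 0.94±0.20 and 1.06±0.18. ERS2 and ERS1 rose at all times (1.3±0.16 and 0.65±0.09 at 1 h), EBF1 and CTR1 at 1 h (0.76±0.19 and 0.46±0.12) and at 24 h. Of 18 signalling genes 9, 7 and 9 rose and 0 fell (9, 8 and 11 higher and 1, 1 and 0 lower over the list alone; the 7 ranged from 4 to 8 with single libraries left out). Camera gave an adjusted p of 3.45e-10, 9.08e-05 and 9.04e-10 (adjusted p = 0.0176, 0.0835 and 0.0176 with an estimated correlation). ERF11 rose by 1.86±0.34, 1.63±0.36 and 2.58±0.33 and ORA59 by 2.65±0.38 at 24 h, with 5, 1 and 5 of 15 response factor genes higher and 0 lower. ACO1 rose by 1.5±0.21, 1.26±0.22 and 1.27±0.21, and PR4 and HCHIB by 2.61±0.28 and 1.24±0.37 at 24 h.

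Some clock genes rose in Col-0 in ethylene. GI rose by 1.14±0.14, 1.22±0.15 and 1.08±0.14 and PRR9 by 2.58±0.34, 2.79±0.36 and 2.33±0.34, with 2, 4 and 6 of 13 clock genes higher and 0 lower (4, 6 and 9 over the list alone; the 4 ranged down to 2). At 24 h the camera adjusted p was 2.08e-08 (adjusted p = 0.0345 with an estimated correlation). MYB12, a regulator of flavonol synthesis, rose by 1.17±0.20, 0.99±0.22 and 1.12±0.20 and MYB11 by 2.68±0.71 at 1 h. Of the auxin genes YUC8 (1.04±0.18, 0.77±0.19 and 1.15±0.18), YUC3 (1.22±0.22 at 1 h) and IAA2 (1.42±0.18, 0.94±0.19 and 1.3±0.18) rose, and ABCB4 fell (−1.39±0.19 at 4 h). Low-oxygen genes fell in 3 of 15 cases at 4 h (1 to 3 with single libraries left out) and at 24 h and 0 rose: ERF71 (−3.20±0.72 and −3.0±0.61), the decarboxylase gene AT4G33070 (−2.03±0.40 and −1.73±0.34) and the lactate dehydrogenase gene AT4G17260 (−1.41±0.21 and −0.90±0.18), with a camera adjusted p of 0.00108 and 0.00022 (adjusted p = 0.211 and 0.144 with an estimated correlation). ARR3 and ARR4 fell at 1 h (−1.31±0.23 and −0.67±0.10). Root hair genes were called in 0, 0 and 2 of 19 cases, RSL2 (−1.58±0.42) and LRL3 (−1.14±0.29), and the 2 ranged from 0 to 2. In the touch list WRKY40 rose at 1 h (1.5±0.34), among nitrate genes RFNR2 fell (−0.70±0.17 at 4 h), and 0 of 13 mitotic genes was called by edgeR.

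Outside the lists the heat factor gene HSFA2 rose by 4.41±0.66 at 1 h, with ORS1 (3.58±0.31), AT5G40590 (3.1±0.36) and WOX11, a homeobox gene of root formation (3.08±0.26). At 4 h, with 2 Col-0 libraries, AT1G21140 and AT3G25190 of the vacuolar iron transporter family rose by 4.53±0.61 and 3.38±0.62 and the ferritin gene FER1 by 3.05±0.21, beside AT1G21320 (3.5±0.29). At 24 h AT4G33720 went from 3 to 260 counts, 74.9-fold with a 95% counting interval of 25.3 to 366, and AT3G05950 (6.08±0.69), AT5G19890 (4.36±0.53) and the potassium transporter gene HAK5 (4.16±0.90) rose. AT2G14247 (−1.66±0.36), CYP82F1 (−1.51±0.40), AT1G01570 (−1.44±0.26) and AT2G48080 (−1.40±0.26) fell at 1 h, AT2G30766 (−3.86±0.89), AT1G13609 (−3.67±0.89), AT3G54530 (−3.56±0.48) and AT2G38823 (−3.52±0.53) at 4 h, and CYP82C4 (−5.06±1.05), AT5G52940 (−4.73±0.68), NDB4 (−4.48±0.63) and AT5G09570 (−4.30±0.39) at 24 h.

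In total 2144 of 20640 genes changed in Col-0 in ethylene (5363 before adjustment), with 327 higher and 157 lower at 1 h, 229 and 282 at 4 h, and 699 and 561 at 24 h. The count was 1235 without Col-0 24 h replicate 2 and otherwise at most 2472. Per time the counts went down to 197, 45 and 393 higher (without 0 h replicate 2, 4 h replicate 3 and 24 h replicate 2) and 50, 32 and 303 lower (without 1 h replicate 2, 4 h replicate 3 and 24 h replicate 2), and up to 281 lower at 1 h without 0 h replicate 3. It was 757 without the shoot-rich libraries, which left 2 Col-0 libraries at 0 h, 1 at 1 h and 1 at 4 h, with 55 higher and 4 lower at 1 h, 37 and 20 at 4 h, and 333 and 300 at 24 h. A fit over the Col-0 libraries alone gave 496, a fit over both series 4001 and limma voom 7681. Shoot markers averaged 5.16±3.19 log2 CPM at 0 h, 7.58±1.06 at 1 h, 7.33±1.55 at 4 h and 5.66±1.44 at 24 h, with 0 of 15 called and a camera adjusted p of 0.000187 at 1 h (adjusted p = 0.588 with an estimated correlation).

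**Figure D3:**
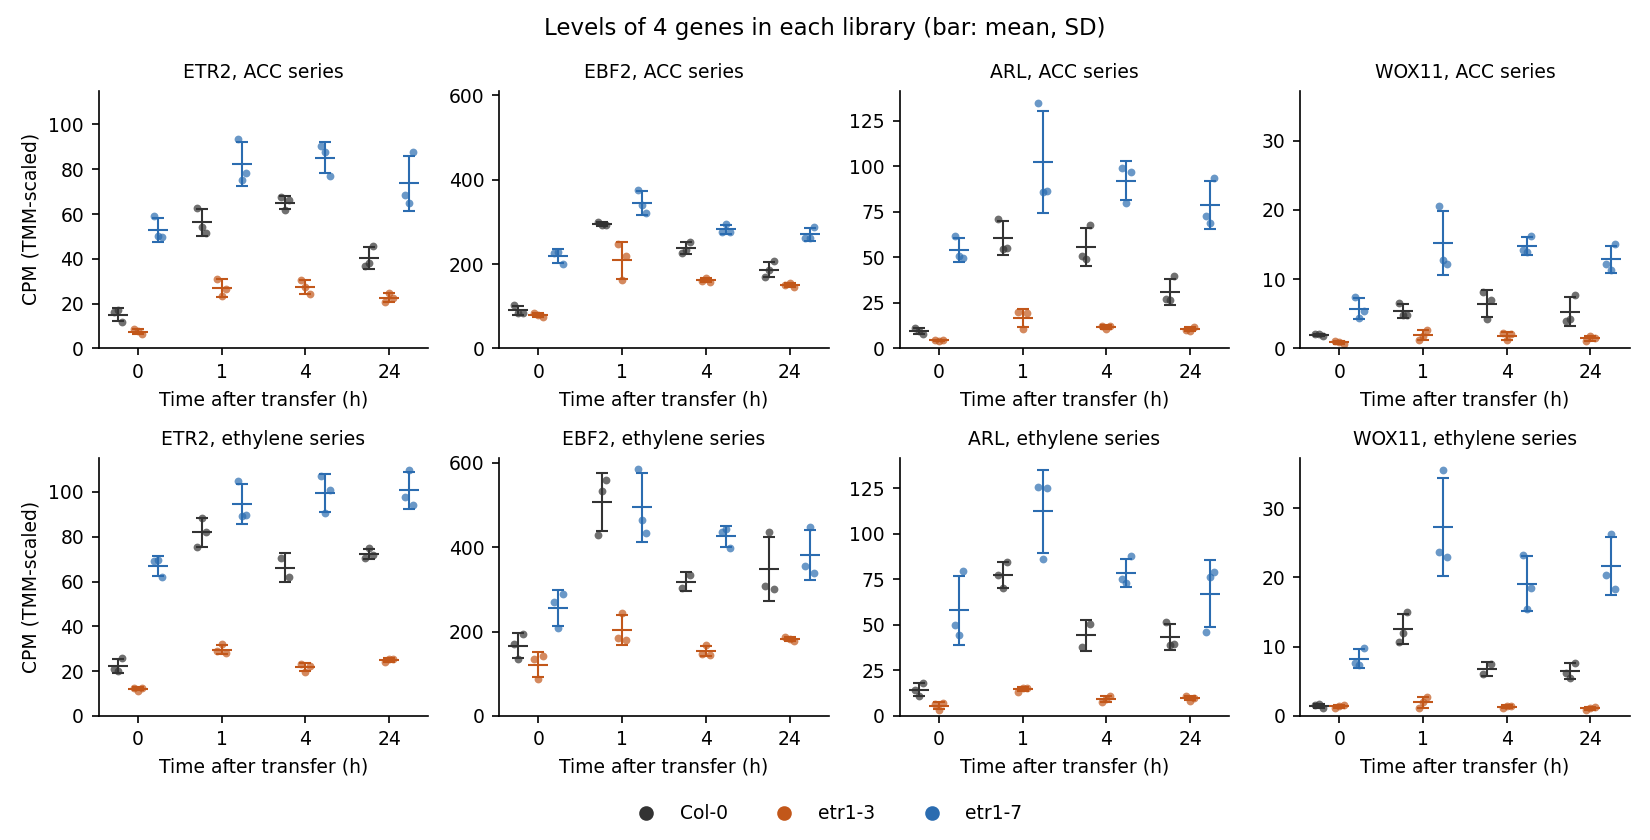
CPM of ETR2, EBF2, ARL and WOX11 (y axis) in each library by hours after transfer (x axis), by genotype and series, with mean and SD. WOX11 went from 1.47±0.27 CPM at 0 h to 12.6±2.22 at 1 h of ethylene in Col-0, and from 1.37 to 1.98 in etr1-3.

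In etr1-3 in ethylene, ETR1 stayed at 49.4±3.78, 46.9±4.19 and 53.2±4.84 CPM and was not called. Of 18 signalling genes 5, 2 and 3 rose and 0 fell (7, 4 and 12 over the list alone, and the 5, 2 and 3 ranged from 2 to 6, 1 to 2 and 2 to 5 with single libraries left out). ETR2 rose by 1.29±0.10, 0.84±0.10 and 1.05±0.10, ARL by 1.41±0.26, ARGOS by 1.52±0.35 and EBF2 by 0.74±0.18 at 1 h, ERS1 by 0.47±0.09 at 1 h and ERS2 by 0.84±0.16 and RAN1 by 0.57±0.17 at 24 h. For this list the camera adjusted p was 6.96e-07, 0.000945 and 2.03e-07 (adjusted p = 0.0369, 0.135 and 0.0338 with an estimated correlation). GI rose by 1.42±0.14, 1.12±0.14 and 1.26±0.14, PRR9 by 2.40±0.34, 2.26±0.34 and 2.37±0.34, and MYB12 by 1.26±0.20, 0.96±0.20 and 1.15±0.20. ORA59 rose by 2.16±0.50 and 2.87±0.48 at 4 and 24 h, and the hook gene HLS1 fell by 1.82±0.35 at 24 h. ARR3 fell by 1.88±0.23 at 1 h with 3 of 10 type-A genes lower (camera adjusted p = 8.53e-11, adjusted p = 0.0542 with an estimated correlation), and ERF71 by 3.43±0.64 at 4 h.

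Outside the lists HSFA2 (4.88±0.68) and the heat shock gene AT1G07400 (3.18±0.67) rose in etr1-3 at 1 h, AT1G21140 (4.51±0.58) and AT1G76800 (3.45±0.42) at 4 h, and AT3G05950 (4.15±0.94) and AT1G64370 (3.5±0.40) at 24 h. AT1G23160 (−2.79±0.61) and AT5G51470 (−2.17±0.45) fell at 1 h, AT1G13609 (−4.41±0.82) and AT3G54530 (−3.84±0.41) at 4 h, and the chaperone gene BIP3 (−6.23±1.52) and NDB4 (−4.32±0.65) at 24 h. In total 1676 genes changed (4822 before adjustment), with 192 higher and 33 lower at 1 h, 71 and 105 at 4 h, and 501 and 343 at 24 h. The count was 787, 955 and 986 without etr1-3 24 h replicates 1, 2 and 3, and 984 without shoot-rich libraries, and it was 2592 with DESeq2, 3469 in a fit over both series and 7918 with limma voom. Per time the counts went down to 72, 35 and 180 higher (without 0 h replicates 2 and 3 and 24 h replicate 1) and 15, 58 and 101 lower (without 1 h replicate 1, 0 h replicate 1 and 24 h replicate 1). Shoot markers averaged 4.34±1.02 log2 CPM at 0 h and 6.54±1.40, 6.25±1.16 and 5.55±0.93 later.

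In etr1-7 in ethylene, ETR1 was at 55.7±7.07, 48.7±11.3 and 67.4±19.5 CPM and was not called. ETR2 rose by 0.50±0.10, 0.57±0.10 and 0.59±0.10, RTE1 by 0.76±0.14 at 1 h and 0.98±0.14 at 24 h, ERS2 by 0.78±0.15, 0.66±0.15 and 0.86±0.15, EBF2 by 0.95±0.18, 0.73±0.18 and 0.57±0.18, and ARGOS and ARL by 1.52±0.31 and 0.95±0.24 at 1 h. EBF1 rose at 4 h (0.70±0.19), ERS1 at all times (0.33±0.08 at 1 h) and EIN2 at 24 h (0.36±0.09). Of 18 signalling genes 7, 5 and 7 rose and 0 fell (8, 6 and 8 over the list alone; the 5 ranged from 1 to 6 and the last 7 from 4 to 8). The camera adjusted p was 5.93e-08, 0.000275 and 2.67e-06 (adjusted p = 0.0281, 0.103 and 0.0531 with an estimated correlation). Of 17 auxin-responsive genes 6, 1 and 7 rose (7, 5 and 8 over the list alone, and the 6 ranged from 2 to 6), with IAA2 at 1.56±0.18, IAA14 at 1.0±0.21 and IAA30 at 1.5±0.31 at 1 h and WES1 at 1.75±0.19 at 24 h. The camera adjusted p at 1 h was 8.53e-11 (adjusted p = 0.0248 with an estimated correlation), and that of auxin synthesis and transport 5.30e-08 (adjusted p = 0.0176 with an estimated correlation; YUC3 1.64±0.22, TAA1 0.95±0.15).

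Expansin and wall genes fell at 24 h, EXPA17 by 3.49±0.41, XTH17 by 3.20±0.42 and XTH31 by 1.54±0.17, with 6 of 16 cell wall genes lower and 0 higher (camera adjusted p = 2.39e-06, adjusted p = 0.0835 with an estimated correlation). The ACC synthase gene ACS9 rose by 3.28±0.78 at 4 h and 4.68±0.79 at 24 h, GI by 1.60±0.14 and PRR9 by 2.55±0.34 at 1 h, and ERF71 fell by 4.31±0.68 at 24 h. HSFA2 (4.34±0.65) and the coactivator gene MBF1C (3.57±0.45) rose at 1 h, AT3G25190 (4.34±0.63) and FER1 (3.95±0.21) at 4 h, and AT4G33720 (9.54±0.91) and AT3G05950 (3.75±0.54) at 24 h. AT2G14247 (−2.29±0.37) and AT1G47395 (−2.05±0.47) fell at 1 h and AT2G04070 (−4.38±0.73) and AT2G38823 (−4.26±0.48) at 4 h, while at 24 h AT5G36130 went from 43 counts to 0, at least 15.1-fold lower, and CYP716A2 from 28 to 0, at least 9.84-fold lower against a floor of 3 counts. In total 2980 genes changed (5804 before adjustment), with 355 higher and 95 lower at 1 h, 201 and 267 at 4 h, and 603 and 847 at 24 h, 2843 without shoot-rich libraries and 2007 to 3066 with single libraries left out, 4760 in a fit over both series and 6059 with limma voom. Per time they went down to 175, 66 and 330 higher (without 0 h replicate 2, 4 h replicate 3 and 0 h replicate 1) and 45, 89 and 502 lower (without 1 h replicate 3, 4 h replicate 3 and 0 h replicate 1).

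The difference between etr1-3 and Col-0 in ethylene came down to 1 gene (630 before adjustment; DESeq2 3, limma voom 5). WOX11 rose less in etr1-3 by 2.57±0.38 log2 units at 1 h (edgeR adjusted p = 0.0061) and by 2.48±0.39 at 24 h (edgeR adjusted p = 0.019). The signalling genes as a list responded less at 1 h (median −0.25, camera adjusted p = 3.84e-06, adjusted p = 0.185 with an estimated correlation; 2 of 18 lower over the list alone), and so did the response factor genes (median −0.25, camera adjusted p = 0.000217, adjusted p = 0.377 with an estimated correlation). The count was 0 without Col-0 0 h replicate 1, 2 or 3 or etr1-3 0 h replicate 2 or 3, and 2 without etr1-3 1 h replicate 3 or 4 h replicate 1. Without shoot-rich libraries 1 Col-0 library was left at 1 h, too few for a test. WOX11 then stood at 10.7 CPM there against 1.61 and 1.64 at 0 h, and in etr1-3 at 1.2 and 1.97 against 1.08, 1.48 and 1.56. Of differences simulated as on ACC, 55.2% were recovered at 2-fold and 83.3% at 4-fold, with the same limits (100 genes called). At 1.5-fold 10.4% were, so smaller ones were mostly beyond reach.

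For etr1-7 in ethylene 17 genes differed from Col-0 (1908 before adjustment; DESeq2 108, limma voom 997). ETR2 rose less at 1 h (−1.37±0.14), 4 h (−1.0±0.15) and 24 h (−1.11±0.14), AT1G21320 less at 4 h (−2.88±0.36), and EXPA17 (−3.29±0.53), the germin-like gene AT5G38940 (−2.97±0.48) and AT2G39530 (−2.82±0.45) were lower at 24 h. AT2G38430 was higher at 24 h (1.91±0.31). The signalling list was lower at 1 h (median −0.17, camera adjusted p = 0.002, adjusted p = 0.377 with an estimated correlation), with 1 of 18 called at each time and 2 over the list alone. Auxin-responsive genes were higher at 24 h (median 0.76, camera adjusted p = 8.86e-09, adjusted p = 0.185 with an estimated correlation; 2 of 17 over the list alone and 0 over all genes). The 17 became 11 without Col-0 0 h replicate 2, 10 without etr1-7 1 h replicate 3 or 4 h replicate 2, 9 without Col-0 1 h replicate 2 or 3 or etr1-7 1 h replicate 1, and 7 without etr1-7 24 h replicate 1 or 3. They became 6, 3 and 27 without Col-0 24 h replicates 1, 2 and 3, 3 without etr1-7 24 h replicate 2, and 1 without shoot-rich libraries.

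A score over the genes of Col-0 in the other series compared the size of the response without a threshold on each mutant. On ACC, Col-0 reached 0.65±0.03, 0.73±0.03 and 0.65±0.05 log2 units at 1, 4 and 24 h, etr1-3 0.50±0.08, 0.65±0.01 and 0.54±0.07, and etr1-7 0.54±0.05, 0.60±0.04 and 0.53±0.10. The difference of etr1-3 from Col-0 was −0.15, −0.08 and −0.10 (two-sided exact permutation p = 0.1, 0.1 and 0.2, n = 3 each) and that of etr1-7 −0.11, −0.13 and −0.12 (exact p = 0.1, 0.1 and 0.2). In ethylene Col-0 reached 0.58±0.09, 0.49±0.01 (n = 2) and 0.59±0.05, etr1-3 0.48±0.08, 0.34±0.06 and 0.25±0.02, and etr1-7 0.37±0.01, 0.37±0.05 and 0.53±0.13. Differences were −0.10, −0.15 and −0.34 for etr1-3 (exact p = 0.2, 0.1 and 0.1) and −0.21, −0.13 and −0.06 for etr1-7 (exact p = 0.1, 0.1 and 0.6). Measured against the Col-0 0 h libraries instead, the differences of etr1-7 turned positive (0.172, 0.071 and 0.124 on ACC, 0.037, 0.339 and 0.295 in ethylene), and those of etr1-3 did not. With 3 libraries per group no exact p can fall below 0.1, so no difference of score could pass on its own. These p and SD leave out the spread of the 0 h libraries. The scores used 484, 511 and 1259 genes in the ACC series and 1063, 2449 and 2453 in the ethylene series.

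**Figure D4:**
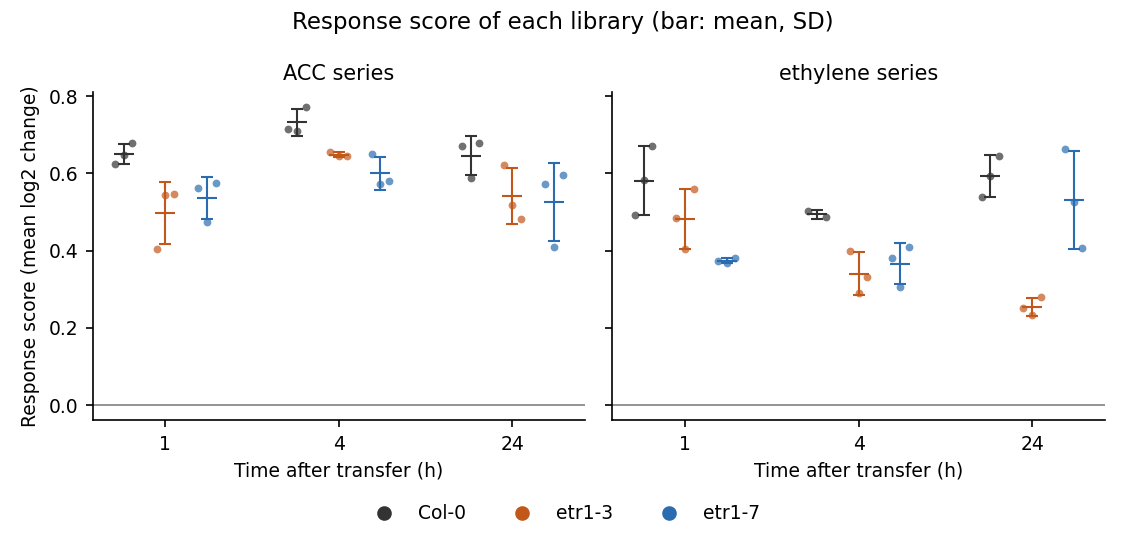
Response score (y axis, mean log2 change over genes called in Col-0 of the other series) of each library at 1, 4 and 24 h after transfer (x axis), with mean and SD. At 24 h of ethylene etr1-3 stood at 0.25±0.02 against 0.59±0.05 in Col-0.

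ACC and ethylene shared many of the Col-0 calls. At 1 h 156 of 567 and 327 genes were higher in both series where independent lists would share 9.12, and 55 of 496 and 157 were lower in both, against 3.83. At 4 h 107 genes were higher in both (11.1 by independence) and 144 lower (20.3), and at 24 h 346 higher (40.9) and 294 lower (34.8), with a Fisher p of at most 1.05e-48 over 20320 genes. EBF2, ETR2, ARL, ARGOS, RTE1 and ERS2 were in the shared higher set at all 3 times. Within series, mutant and Col-0 share no library, but 1 fit gives both the same spread per gene. A gene with a low spread passes more easily in both, so independence is only a rough reference there. At 1 h of ACC 334 of 478 higher genes of etr1-3 were also higher in Col-0 (13.3 by independence) and 557 of 964 at 24 h (56.4). In ethylene these were 140 of 192 at 1 h (3.04) and 240 of 501 at 24 h (17). For etr1-7 they were 197 of 260 (7.23) and 464 of 904 (52.8) on ACC, and 187 of 355 (5.62) and 298 of 603 (20.4) in ethylene. Over all 30 overlaps and 6 settings the ratio to independence was at least 5.61.

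A direct test asked where ACC and ethylene differed in Col-0, each against its own 0 h. ETR1 was not called. ETR2, EBF2 and ARL were not called (ARL 0.92±0.35 at 4 h), while the clock genes GI (−0.94±0.20, −1.11±0.21 and −1.03±0.20 at 1, 4 and 24 h) and PRR9 (−2.25±0.42 and −2.16±0.43 at 1 and 4 h) were lower on ACC. Clock genes were lower as a list at 1, 4 and 24 h (2, 2 and 1 of 13 lower, both counts of 2 from 0 to 2 with single libraries left out, 4, 4 and 3 over the list alone; camera adjusted p = 6.05e-07, 6.39e-06 and 4.44e-07, adjusted p = 0.0213, 0.0362 and 0.0213 with an estimated correlation). GI stood at 57.2±3.92 CPM in Col-0 at 0 h of the ACC series and 32.6±2.18 at 0 h of the ethylene series but at 66.5 and 72.0 at 1 h, so the difference of response lies largely in the 0 h level. Low-oxygen genes were higher on ACC at 24 h (median 0.99, camera adjusted p = 9.34e-06, adjusted p = 0.0415 with an estimated correlation) and at 4 h (median 1.13, camera adjusted p = 3.01e-05, adjusted p = 0.057 with an estimated correlation), with 0 of 15 called by edgeR at either time and 0 and 2 over the list alone. TCH3 was higher at 4 and 24 h (2.97±0.59 and 2.46±0.54) and YUC8 lower at 24 h (−1.11±0.21).

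Outside the lists AT5G48430 was higher on ACC at 1, 4 and 24 h (2.66, 3.26 and 2.60), AT5G38850 at 1 h (0.91), AT5G40590 (3.31) and AT1G13480 (3.12) at 4 h, and AT5G36130 (3.48) at 24 h. BBX30, a B-box gene, was lower at all times (−3.26, −2.93 and −2.35), MBF1C at 1 h (−2.42), AT3G57540 (−2.27) and AT2G41170 (−2.18) at 4 h, and SIGE (−1.77) and AT3G56290 (−1.60) at 24 h. In total 39 of 20908 genes differed (1675 before adjustment), with 2 higher and 14 lower at 1 h, 7 and 14 at 4 h, and 5 and 11 at 24 h. DESeq2 called 117 and limma voom 1047. The 39 became 22, 17 and 23 without ACC Col-0 0 h replicates 2, 3 and 4, 9 and 23 without ethylene Col-0 0 h replicates 2 and 3, 24 without ethylene Col-0 4 h replicate 3, and 3 without shoot-rich libraries. The series also differ in everything that was not shared between them, which may include the day, though the labels name none. Such differences were not analysed here.

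At 0 h the question was how the mutants differ before treatment. ETR1 was not called in etr1-3. Of its 18 ethylene signalling genes 3 were lower than in Col-0, ETR2 by 0.94±0.10 (7.52±0.989 CPM against 15.0±2.78 in the ACC series and 12.1±0.749 against 22.4±3.18 in the ethylene series), ARL by 1.26±0.19 and ARGOS by 1.3±0.22, and 1 was higher, ETP1 by 0.36±0.07 (7 lower and 1 higher over the list alone; camera adjusted p = 1.84e-08, adjusted p = 0.187 with an estimated correlation). Of 19 root hair genes 2 were lower, XTH13 by 1.15±0.18 and PRP1 by 1.34±0.21 (2 to 9 with single libraries left out, 12 over the list alone; camera adjusted p = 6.92e-12, adjusted p = 0.5 with an estimated correlation). ORA59 (−2.21±0.37), EIL2 (−1.56±0.24), XTH26 (−2.22±0.28), AT5G19890 (−2.21±0.41), the carbonic anhydrase gene BCA3 (−1.62±0.32) and ICME-LIKE1 (−1.45±0.09) were lower. The largest falls were those of AT5G41660 (−7.26±0.38) and MRD1 (−6.07±0.40), which stayed low in etr1-3 at all times. AT5G41660 was also much lower in etr1-7 than in Col-0 at 0 h, so its difference is not particular to etr1-3.

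Higher in etr1-3 at 0 h were SP1L5 (1.23±0.24), AT2G13550 (1.0±0.12), AT1G65370 (0.94±0.16), the cytokinin oxidase gene CKX6 (0.92±0.17), the auxin synthesis gene YUC5 (0.88±0.18), AT2G24945 (0.84±0.13), AT3G44940 (0.82±0.15) and TBL36 (0.67±0.11), with the clock gene PRR7 (0.50±0.10). In total 46 of 20073 genes differed (1849 before adjustment; DESeq2 186, limma voom 411), 14 higher and 32 lower, with 6 libraries per genotype. The 46 became 25 without ACC Col-0 replicate 2 or ethylene Col-0 replicate 2, 26 and 30 without ACC etr1-3 replicates 3 and 4, 29 and 30 without ethylene etr1-3 replicates 1 and 3, and 190 without ethylene Col-0 replicate 3, the shoot-rich library of 0 h. The ACC series alone gave 52 genes and the ethylene series alone 19.

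In etr1-7 at 0 h 11 of 18 signalling genes stood higher than in Col-0. ETR1 had opposite differences in the 2 series and was not called. ETR2 was higher by 1.7±0.10 (53.0±5.28 CPM in the ACC series and 66.9±4.32 in the ethylene series), ARL by 2.26±0.18, ARGOS by 2.27±0.21, RTE1 by 1.40±0.10, ERS2 by 0.99±0.14, EBF2 by 0.95±0.14, ERS1 by 0.67±0.08, CTR1 by 0.39±0.07, EIL1 by 0.37±0.09, EBF1 by 0.28±0.09 and EIN2 by 0.25±0.08, and the receptor gene EIN4 was lower by 0.97±0.08. Over the list alone 11 were higher and 3 lower (camera adjusted p = 0.000145, adjusted p = 0.5 with an estimated correlation). ORA59 (2.47±0.28), ERF11 (1.68±0.27), EDF3 (1.29±0.22) and TEM1 (0.85±0.13) were higher, 7 of 13 response factor genes with 0 lower (camera adjusted p = 0.00152, adjusted p = 0.566 with an estimated correlation). ACO1 (1.47±0.14) and AT1G12010 (2.33±0.22) were higher and ACS2 (−1.43±0.19) lower. Root hair genes went both ways, 3 higher (XTH13 1.02±0.18) and 2 lower (RSL2 −1.38±0.33) of 19, and of 17 auxin-responsive genes 16 were tested, 3 higher and 7 lower (4 to 9 with single libraries left out). PR4 was higher (1.17±0.14), and VSP1 (−2.46±0.38), VSP2 (−2.92±0.59) and HCHIB (−0.87±0.21) were lower. Clock genes were lower in 5 of 13 cases (RVE1 −0.91±0.14; 1 to 5 with single libraries left out).

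Outside the lists AT3G02670 (7.05±0.70), AT1G27565 (5.64±0.28), AT1G49570 (5.47±0.60), AT5G19890 (5.39±0.31), AT1G73610 (4.69±0.53), AT3G05950 (4.51±0.56), AT1G21320 (4.14±0.24) and BCA3 (3.85±0.28) were higher in etr1-7. AT5G41660 (−7.80±0.40), BGLU7 (−5.06±0.66), AT2G16005 (−4.72±0.40), EXPA2 (−4.42±0.47), AIR1 (−4.22±0.56), AT4G36600 (−3.89±0.77), AT1G55990 (−3.65±0.28) and AT3G21670 (−3.59±0.31) were lower. In total 4176 genes differed (6733 before adjustment), 1877 higher and 2299 lower. The count lay between 3344 and 6079 with single libraries left out, 6079 being that without the shoot-rich ethylene Col-0 replicate 3, the ACC series alone gave 5797 and the ethylene series alone 1637, and limma voom gave 6419. Shoot markers averaged 3.07±0.27 log2 CPM in etr1-7 against 4.46±1.02 in Col-0 at 0 h of the ACC series, and 4.9±2.56 against 5.16±3.19 in the ethylene series.

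The 2 series already differed at 0 h. Root hair genes were higher in the ACC series in 16 of 19 cases and 0 lower (17 over the list alone; LRX2 0.75±0.08, PRP1 1.34±0.17, XTH13 1.12±0.15), with a camera adjusted p of 2.79e-13 (adjusted p = 0.208 with an estimated correlation). Auxin-responsive genes were higher in 7 of 16 cases (IAA1 0.78±0.11, WES1 0.63±0.11; camera adjusted p = 4.72e-05, adjusted p = 0.208 with an estimated correlation) and cell wall genes in 8 of 16 (XTH19 0.54±0.08; camera adjusted p = 0.00232, adjusted p = 0.208 with an estimated correlation). GI (1.2±0.09), PRR9 (1.66±0.20) and MYB12 (0.83±0.07) were higher, 4 of 13 clock genes (camera adjusted p = 0.0168, adjusted p = 0.223 with an estimated correlation). ETR2 (−0.49±0.08), EBF1 (−0.47±0.08), EBF2 (−0.54±0.12), TCH3 (−1.14±0.28) and HLS1 (−0.99±0.17) were lower. In total 4815 genes differed (7786 before adjustment), 2645 higher and 2170 lower, 4636 without the shoot-rich library and 3837 to 5225 with single libraries left out, from 9 libraries of each series.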

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

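These results passed a test of the difference itself, between mutant and Col-0 or ACC and ethylene. Values are differences of 2 log2 changes from 0 h. Splits leave chance open for these gene counts, all lower without shoot-rich libraries. Between etr1-7 and Col-0 on ACC 8 genes differed. At 1 h UGE2 was higher (1.13) and ARL (−1.74), ETR2 (−1.26) and EBF2 (−1.04) were lower, and at 4 h P5CS1 was higher (1.04) and AT1G49570 (−3.05), AT2G43140 (−2.54) and ARL (−1.78) were lower. Between etr1-3 and Col-0 in ethylene 1 gene differed, WOX11, lower at 1 h (−2.57) and at 24 h (−2.48). Between etr1-7 and Col-0 in ethylene 17 genes differed. ETR2 was lower at 1 h (−1.37) and, with AT1G21320 (−2.88), at 4 h (−1.0), and at 24 h AT2G38430 was higher (1.91) and EXPA17 (−3.29), AT5G38940 (−2.97) and AT2G39530 (−2.82) were lower.

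Between the ACC and the ethylene response of Col-0, which come from 2 separate experiments, 39 genes differed. Higher on ACC were AT5G48430 (2.66, 3.26 and 2.60 at 1, 4 and 24 h), AT5G38850 (0.91 at 1 h), AT5G40590 and AT1G13480 (3.31 and 3.12 at 4 h), and AT5G36130 and TCH3 (3.48 and 2.46 at 24 h). Lower on ACC were BBX30 (−3.26, −2.93 and −2.35 at 1, 4 and 24 h), MBF1C and PRR9 (−2.42 and −2.25 at 1 h), AT3G57540 and AT2G41170 (−2.27 and −2.18 at 4 h), and SIGE and AT3G56290 (−1.77 and −1.60 at 24 h). Clock genes were lower on ACC as a list, with medians of −0.38, −0.38 and −0.30 at 1, 4 and 24 h (adjusted p = 0.0213, 0.0362 and 0.0213 with an estimated correlation), and low-oxygen genes were higher at 24 h, with a median of 0.99 (adjusted p = 0.0415 with an estimated correlation).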

How the results depend on the processing

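The shoot marker covariate, the fits without shoot-rich libraries, the score against the Col-0 0 h libraries and leaving out single libraries in the scores were chosen after the results were seen. In the tests by DESeq2, 2592 genes changed in etr1-3 in ethylene (1676 with edgeR), 14 and 61 differed for etr1-3 and etr1-7 on ACC (0 and 8), 3 and 108 in ethylene (1 and 17), 117 between ACC and ethylene (39) and 186 between etr1-3 and Col-0 at 0 h (46). With limma voom the time courses of etr1-3 and etr1-7 on ACC gave 7497 and 7561 genes (4659 and 3479), those of Col-0, etr1-3 and etr1-7 in ethylene 7681, 7918 and 6059 (2144, 1676 and 2980), the differences of etr1-3 and etr1-7 2 and 79 on ACC and 5 and 997 in ethylene, ACC against ethylene 1047, and etr1-3 and etr1-7 at 0 h 411 and 6419. Its share of higher genes also differed, with 1925 higher and 2057 lower at 1 h in Col-0 in ethylene (327 and 157 with edgeR) and 971 and 862 at 1 h in etr1-3 on ACC (478 and 218). A fit over all libraries of both series gave 3414 and 2019 genes for Col-0 and etr1-7 on ACC, 4001, 3469 and 4760 for Col-0, etr1-3 and etr1-7 in ethylene, and 2 and 93 for the differences of etr1-3 and etr1-7 in ethylene. A fit over the compared libraries only gave 2477 and 1786 for etr1-3 and etr1-7 on ACC, 496 for Col-0 in ethylene, and 0 and 6 for these 2 differences. DESeq2 size factors and no filter each gave 4 for the difference of etr1-7 on ACC. Without shoot-rich libraries 757 and 984 genes changed in Col-0 and etr1-3 in ethylene, 1 and 3 differed on ACC and 0 and 1 in ethylene for etr1-3 and etr1-7, 3 between ACC and ethylene, and 190 between etr1-3 and Col-0 at 0 h (24 higher and 166 lower). In Col-0 in ethylene they left 55 higher and 4 lower at 1 h and 37 and 20 at 4 h, where a lone library is assumed to vary like the other groups. The shoot marker covariate gave 13 for etr1-7 on ACC, 85 for etr1-3 at 0 h, and 404 higher and 100 lower at 1 h and 355 and 277 at 4 h in Col-0 in ethylene. The ethylene series alone gave 19 and 1637 genes for etr1-3 and etr1-7 at 0 h, and the ACC series alone 52 and 5797.

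With the replicate number as a block, 29 and 30 genes differed for etr1-7 on ACC and in ethylene and 116 between ACC and ethylene. Between etr1-3 and Col-0 at 0 h 81 genes differed. For the series at 0 h the block changed the contrast itself, since the numbers are nested in series. It set ACC replicate 2 against ethylene replicate 1, with 1434 genes called and AT1G25550 at −0.01 (main value 0.28). These 2 values therefore cannot be compared with the main test of the series. The labels do not say what the number marks, and not every pair of libraries with the same number had r over 0.1: 121 of 198 on ACC and 94 of 187 in ethylene did, with lows of −0.15 and −0.37. The mean r was 0.12 in both series, against −0.061 and −0.06 for other numbers, and 31 of 36 and 24 of 35 libraries were closest to their own number, a hint from the data of structure shared by number.

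The direction of some list tests changed, each to an adjusted p above 0.4. These were the root hair list in the difference of etr1-3 at 4 h of ethylene without shoot-rich libraries (camera adjusted p = 0.417, and 0.0101 with all libraries) and, with the shoot marker covariate, the shoot list in etr1-7 on ACC at 1 and 24 h (0.517 and 0.985), the difference of etr1-3 on ACC at 4 h (0.847), Col-0 in ethylene at 1 and 4 h (0.961 and 0.948) and etr1-3 in ethylene at 4 h (0.946), which the covariate removes by construction. With an estimated correlation 16 gene list tests were called (198 at the preset one), and 173 to 207 in the other settings. Against the Col-0 0 h libraries the score of etr1-7 lay over that of Col-0, by 0.172, 0.071 and 0.124 at 1, 4 and 24 h of ACC and 0.037, 0.339 and 0.295 of ethylene, since its 0 h level was higher. Leaving out single libraries, its difference at 24 h of ethylene went from −0.126 (without etr1-7 24 h replicate 1) to 0.001 (without etr1-7 24 h replicate 3). The score of etr1-3 lay below that of Col-0 in all 14 settings of each time, 13 at 4 h of ethylene, with differences from −0.455 to −0.054.

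Leaving out single libraries gave 4035 to 4763, 3089 to 5104 and 2327 to 4319 genes for Col-0, etr1-3 and etr1-7 on ACC, and 1235 to 2472, 787 to 1877 and 2007 to 3066 in ethylene. The differences gave 0 to 1 and 2 to 18 on ACC and 0 to 2 and 3 to 27 in ethylene for etr1-3 and etr1-7, 9 to 50 for ACC against ethylene, and at 0 h 25 to 190 for etr1-3, 3344 to 6079 for etr1-7 and 3837 to 5225 for the series. Of the named genes outside the lists, 2001 of 2302 values kept their call in these fits, 155 of 155 with DESeq2 and 142 of 162 with limma voom. Without shoot-rich libraries 119 of 162 kept it, and in fits over the compared libraries only 92 of 113. At 0 h 21 of 32 kept it in the ACC series alone and 20 of 32 in the ethylene series alone, and 0 changed sign in any setting. Of 186 counts of list members of at least 2, 103 moved by more than 1.5 times when a single library was left out and 83 did not. Of all other values, 480 counts per time moved by more than 1.5 times and 1364 did not, and 1754 values of single genes lost the call and 15307 kept it; the cause was not tested.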

Other observations

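The comparisons of the etr1-3 score with 0 and with that of Col-0, the calls and sizes with the shoot marker covariate, and, for the genes that differ in etr1-3 at 0 h, their directions on ACC and their calls in the etr1-7 time course were chosen after the results were seen. The genes GI and PRR9 of the clock list, SIGE and MYB12, put together after their values were seen, had a low level at 0 h of the ethylene series in all 3 genotypes. Of 13 clock genes 4 were called between the series at 0 h (adjusted p = 0.223 with an estimated correlation). GI stood at 32.6±2.18, 27.2±1.17 and 26.2±4.31 CPM there in Col-0, etr1-3 and etr1-7, and at 57.2±3.92, 66.6±4.77 and 66.7±8.90 at 0 h of the ACC series. SIGE, a plastid sigma factor gene, stood at 12±2.32, 12.1±1.76 and 11.2±3.26 CPM against 30.7±0.809, 29.4±3.39 and 24.0±3.49, and PRR9 at 1.57±0.747, 1.60±0.757 and 1.58±0.0426 against 4.78±0.666, 6.11±2.06 and 3.99±1.06. MYB12 stood at 31.9±2.67, 31.2±2.63 and 33.5±5.09 against 56.1±3.35, 59.7±3.09 and 52.6±8.56. At 1 h of ethylene GI had reached 72.0±9, 72.5±9.20 and 79.5±9.33 CPM and SIGE 31.2±4.23, 31.2±6.40 and 33.7±5.26, levels near those of the ACC series (66.5±4.16 for GI and 25.5±2.91 for SIGE in Col-0 at 1 h). MBF1C, a heat-related coactivator gene, stood at 52.9±17.6, 52.4±7.55 and 54.5±31.8 CPM at 1 h of ethylene in the 3 genotypes and at 18.6±3.79, 24.6±5.07 and 14.5±2.76 at 1 h of ACC.

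Untreated etr1-7 roots were set beside Col-0 roots after 1, 4 and 24 h of treatment, first for 5 genes that stood higher in etr1-7 than in Col-0 at 0 h. Not all response genes did: HCHIB, which rose in Col-0 at 24 h, stood lower in etr1-7 at 0 h. At 0 h of the ACC series etr1-7 held ETR2 at 53.0±5.28 CPM against 56.2±5.99, 65.1±3.02 and 40.2±4.86 in Col-0, ARL at 54.1±6.62 against 60.5±9.36, 56.0±10.4 and 31.1±7.32, RTE1 at 18.3±1.83 against 14.3±2.09, 17.7±3.1 and 16.6±2.71, and EBF2 at 218±16.5 against 295±4.52, 237±14.6 and 187±18.3. WOX11 stood at 5.69±1.53 CPM against 5.42±1.01, 6.43±1.98 and 5.3±2.06. At 0 h of the ethylene series these 5 genes lay below Col-0 after 1 h in their means, and, except EBF2, not below Col-0 after 4 h (2 libraries): ETR2 at 66.9±4.32 against 82±6.56, 66.3±6.28 and 72.4±2.32, ARL at 58.1±19 against 77.5±7.15, 44.2±8.57 and 43.3±7.09, RTE1 at 19.5±1.03 against 21.2±1.02, 16.7±1.23 and 22.3±1.1, WOX11 at 8.24±1.34 against 12.6±2.22, 6.75±0.956 and 6.45±1.11, and EBF2 at 256±42.9 against 508±68.8, 319±21.7 and 348±76.3. In the ACC series AT1G49570, a peroxidase family gene, stood at 212±24.3 in etr1-7 at 0 h and at 6.14±2.22, 30±10.9 and 56.4±36.1 in treated Col-0. On ACC etr1-7 reached 82.2±9.91 CPM of ETR2, 102±28.1 of ARL and 15.1±4.63 of WOX11 at 1 h. The wall genes EXPA17 and XTH17 stood at 1.94±0.734 and 6.11±0.407 CPM in etr1-7 after 24 h of ethylene and at 26±12 and 52.9±16.7 in Col-0, and in etr1-3 XTH17 stood at 85.1±11.6. After 24 h of ACC they stood at 13.8±7.30 and 49.7±5.16 in etr1-7.

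The shoot markers differed by several log2 units between libraries of 1 group. From the library with the lowest to that with the highest mean, RBCS1A went from 10.5 to 2180 CPM and CAB1 from 9.74 to 2170. Greening of the roots as the whole cause was argued against by 11 genes of guard cells, leaf surface and leaf polarity, which do not serve photosynthesis: within groups they rose with the shoot markers with a slope of 0.532±0.044 (r = 0.871, rho = 0.84, permutation p = 1e-05 each, the smallest 1e+05 permutations can give, r = 0.846 without the 2 farthest libraries), and the 11 single slopes ran from 0.30 to 0.79. Library depth was argued against by a weak relation with log2 total count (r = 0.155, rho = 0.189, permutation p = 0.2 each, r = 0.198 without the 2 farthest libraries). Shoot tissue carried into the root samples remains a candidate source, with the same slope of 0.532, although 3 of the 11 genes exceeded 1 CPM even in the library with the lowest shoot markers and 9 in that with the highest.

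In etr1-3, an insensitive allele, many genes moved much as in Col-0. A response of 0 hidden by the spread between replicates was argued against by a score over 0 by more than 2 SD in 6 of 6 combinations of series and time. Col-0 plants in place of etr1-3 were argued against by MRD1, which was lower in 18 of 18 treated libraries labelled etr1-3 than in every Col-0 library of the series (at most 2.09 CPM on ACC and 4.07 in ethylene, against at least 43.1 and 55.6). Transfer to fresh medium and time as the whole cause cannot be told apart from a response to ACC or ethylene that remains in etr1-3, since no untreated library followed 0 h. The score of etr1-3 lay below that of Col-0 by more than 2 times the larger SD in 3 of the 6 combinations.

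At 0 h 46 genes differed between etr1-3 and Col-0, on all 5 chromosomes. Tight clusters of linked DNA from another strain as the source of the set were argued against by 3 pairs of these genes within 50 gene positions, where 10000 random draws had a median of 4. This window cannot detect wider linked stretches, which stay open. It also says nothing of single neighbours such as MRD1 and HEI10, which was looked up after its values were seen (−0.80±0.14). Shoot tissue as the whole cause was argued against by the fit with the shoot marker covariate, which called 85 genes: all 46 kept their direction and 0.95 to 1.05 times their log2 difference (median 0.94 before and 0.92 after), and 45 were still called, while BCA3 went from −1.62±0.32 to −1.59±0.34 and its adjusted p from 0.046 to 0.06 through the larger SE. Ethylene-response genes at a lower starting level remain a candidate. In the Col-0 ACC time course 31 of the 46 (67.4%) were called, against 25.8% of all tested genes (Fisher p = 3.9e-09). By their largest change on ACC, 16 lower at 0 h rose and 7 fell, and 7 higher at 0 h rose and 1 fell. In the etr1-7 ACC time course 15 of the 46 were called (32.6%, odds ratio 2.36, Fisher p = 0.0094). In that order they were 8, 3, 0 and 4. The fits share the ACC 0 h libraries, so genes of low spread pass more easily, and both Col-0 tests use those of Col-0. Calls join ACC with time on new medium.

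Other splits of the same libraries into groups of the same sizes were tested for each count of genes. For the 6 time courses 1 of 100 splits, the real one, gave as many genes. On ACC these were 5248 in Col-0, 4659 in etr1-3 and 3479 in etr1-7 with a highest other count of 13, 419 and 13. In ethylene they were 2144, 1676 and 2980 with 613, 72 and 241. The time labels of all 3 genotypes were exchanged at once, so real changes over time enter the spread of the other splits and can lower their counts. Chance is thus made unlikely for the time courses but is not excluded. The same holds for the series at 0 h, where only the real split of 100 gave as many (4815, highest other 474). For each mutant at 0 h 2 of 100 splits gave as many, the real one and 1 other that called more: 62 against 46 for etr1-3 and 4227 against 4176 for etr1-7. That other split exchanged the shoot-rich ethylene Col-0 replicate 3 with replicate 1 of the mutant. Chance is thus made unlikely for these 2 counts but is not excluded. For the differences of response the splits leave open whether chance gives such counts: on ACC 0 for etr1-3 (edgeR; 915 before adjustment, 14 with DESeq2 and 2 with limma voom; 100 of 100 splits gave as many, highest other 222) and 8 for etr1-7 (6 of 100, 4819), in ethylene 1 for etr1-3 (12 of 100, 179) and 17 for etr1-7 (8 of 100, 608), and 39 for ACC against ethylene (5 of 40, 2668). A count of 0 is reached by every split, so that test says nothing. Splits with several times the real count point to a structure of the samples. Those of 4819, 179 and 2668 genes exchanged all libraries of 24 h, and that of 222 all libraries of 4 h, which by construction turns a difference present at every time into a difference of response, so these splits do not measure chance alone.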
